A study of Sus scrofa with 8 samples.

How the data were processed

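RNA was measured in left ventricular muscle taken away from the infarct in 8 castrated male Yorkshire pigs after myocardial infarction, with 1 Affymetrix porcine genome array for each animal. Per the labels, total RNA was extracted with Trizol and labelled with biotin. The authors deposited log2 expression values for 24123 probe sets on each array; per the submitters' processing notes the tools were RMA and Partek 6.6, and further settings are not given in the sources used here. RMA corrects background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of each probe set by median polish, so a change shared by most genes of an array would be removed. The deposited log2 values lay between 2.13 and 15.01, with array medians between 5.34 and 5.40. Values below the arrays' lower quartiles of 3.72 to 3.80 were taken as close to background; they hold no order and give no exact size of change, and values close to 15.0 have little room to rise. Arrays carry no read depth, so the number of arrays limits the precision.

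Groups were taken from the treatment named in the labels: 3 untreated animals, 3 animals that received GGF2 at 0.67 mg/kg in each infusion and 2 that received 2.0 mg/kg, in both cases over 4 weeks. The labels name a different pig for each array, so the p-values of single probe sets measure the spread between animals. The labels hold no replicate numbers; those used here follow the order of the samples within a group and pair nothing across groups.

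A total of 124 control probe sets were left out, and 23999 were tested. Gene symbols came from the platform annotation supplied with the data: 10069 probe sets carried 1 symbol, 198 carried several and 13732 carried none. Probe sets with several symbols or none were tested and counted but named no gene. The named probe sets covered 6765 genes. Current symbols in the gene lists were matched to the annotation's older ones (CCN1 to CYR61, for example). No genome was used, and no coordinates are given.

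limma 3.58.1 in R 4.3.3 fitted 1 mean for each group to all 8 arrays, with 5 residual degrees of freedom and 3.50 prior degrees of freedom from the empirical Bayes step. The 4 contrasts were low dose against untreated, high dose against untreated, high dose against low dose, and the mean of both doses against untreated. Benjamini-Hochberg adjustment was applied within each contrast, and an adjusted p under 0.05 counted as passing. Fold changes are differences of log2 values, with the moderated standard error (SE).

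Before the data were examined, 30 gene lists for this tissue and treatment were fixed, holding 799 different genes, of which 557 were measured; 8 of the lists hold markers of other cell types. Each list was tested with camera in limma, with a preset correlation between genes of 0.01, on the brightest probe set of each gene, with Benjamini-Hochberg adjustment over the 30 lists. The preset takes the genes of a list as nearly independent. Its p-values thus leave out most of the variation between animals that the genes of a list share. Each call was therefore set beside camera with the correlation estimated from the data. Members of a list were also adjusted over the list alone. List means per animal are means of the members' log2 values after each gene was centred on its mean over the 8 arrays. They were compared between the 5 treated and 3 untreated animals by an exact permutation test, two-sided, whose smallest possible p is 0.0357. A comparison of 3 animals with 3 cannot go below 0.1 and one of 3 with 2 cannot go below 0.2, so no such test was used within single doses.

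The rule for named genes was also fixed beforehand. For each contrast against untreated it took up to 10 genes in each direction with the largest change among those passing, and 5 in each direction for high against low dose. Places left open were filled by the smallest p among probe sets with a change of at least 1.5-fold and no overlap between the groups' values. Up to 4 members of each passing list with the smallest p were added, as were 11 genes of interest, of which COL3A1, ACTA2, NPPA, NPPB, MYH7 and ATP2A2 were measured. NRG1, ERBB2, ERBB3, ERBB4 and COL1A1 had no probe set with a single symbol of that name and are not analysed here. For a gene with several probe sets, the rule used the one with the smallest p in places filled this way, which was not always the brightest or the one with the largest change, and the list tests used the brightest one. Other probe sets of a named gene that differ and lie above background are given for many of the genes but not for all.

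The alternatives were an intensity trend or a robust variance prior, a filter on dim probe sets, median centring, renewed quantile normalization, fits of only 2 groups, the treated arrays pooled as 1 group, array weights, looser thresholds, the mean of a gene's probe sets, camera on ranks, and leaving out each array in turn. After the data were seen, fits with the immediate early gene mean as a covariate were added. That mean was 1.42 and 1.12 in the high-dose animals and at most 0.52 in any other animal. The covariate thus did not overlap between the high dose and the other groups. Calls kept, gained or lost in these fits rest on extrapolation and do not separate the covariate from the high dose. Fits that set apart the untreated and the low-dose animal with neighbouring tag numbers were added as well.

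The steps were tested on simulated data made from the real means and from the variances after the empirical Bayes step. That step draws the variances towards a common value, so the simulated noise was more even between probe sets than in the data. Of 200 probe sets changed in each of 10 simulations among 23999, the limma step found 71.5% of changes of 1 log2 unit and 98.1% of changes of 2 log2 units in high dose against untreated. For low dose against untreated it found 82.5% and 98.5%. A shift of 0.3 in the fatty acid list was found by camera in 10 of 10 simulations of high dose against untreated on 6765 genes. The simulated genes varied independently, and no simulation with correlated genes was run, so the shares need not hold for real tissue.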

Results

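Glial growth factor 2 (GGF2) is an isoform of neuregulin-1, a growth factor that acts on cardiac muscle through ERBB receptors. The study asked how GGF2 infusion after myocardial infarction changed gene expression in left ventricular muscle remote from the infarct in pigs. The 8 arrays, 1 for each animal, came as follows: 3 from untreated animals, 3 from animals given 0.67 mg/kg GGF2 per infusion (low dose) and 2 from animals given 2.0 mg/kg (high dose), both for 4 weeks. Values are RMA values on the log2 scale. The arrays resembled each other closely, with correlations across probe sets between 0.981 and 0.994, and the median correlation was 0.987 both within groups and between groups. The gap between 3' and 5' control probe sets, a measure of RNA integrity, was 3.11 ± 0.23 log2 units in untreated animals (SD, n = 3), 3.45 ± 0.29 at the low dose (n = 3) and 3.02 ± 0.03 at the high dose (n = 2).

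The comparison of high dose with untreated asked what the larger dose changed. Matrix, macrophage and cell cycle genes were lower in the high-dose animals, and immediate early, heat shock and fatty acid oxidation genes were higher. Immediate early genes, which cells switch on within minutes of a stimulus, rose as a list by a median log2 change of 1.83 over 16 genes (camera adjusted p = 7.02e-10). Other extracellular matrix proteins fell with a median of -0.73 over 21 genes (camera adjusted p = 7.02e-10), and macrophage markers fell with a median of -0.42 over 17 genes (camera adjusted p = 1.93e-05). These 3 calls were lost when camera estimated the correlation between genes, each with an adjusted p = 0.329 with an estimated correlation. No single probe set passed in this comparison: 0 of 23999 had a limma adjusted p under 0.05, the smallest being 0.0505, while 1913 had an unadjusted p under 0.05, against 1200 expected by chance.

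Of the 21 matrix proteins, 20 were lower at the high dose. None passed over all probe sets and 8 passed when adjusted over the list alone. Periostin (POSTN), a matrix protein made by activated fibroblasts, measured 9.54 ± 0.47 in untreated animals (SD, n = 3) and 7.08 ± 0.57 at the high dose (n = 2), a log2 change of -2.46 ± 0.33 (SE; limma adjusted p = 0.104). Fibrillin-1 (FBN1), the main protein of microfibrils, differed by -1.39 ± 0.22 (limma adjusted p = 0.141). The proteoglycans versican (VCAN) and lumican (LUM) differed by -1.60 and -0.90, fibronectin (FN1) by -1.12 and the laminin chain LAMB1 by -0.63, with -0.23 on a less bright LAMB1 probe set. Each of these 6 passed over the list alone. The collagens fell as a list with a median of -0.39 over 9 genes, 7 of them lower (camera adjusted p = 0.0128; adjusted p = 0.329 with an estimated correlation). COL8A1 and COL15A1 passed over the list alone, at -1.09 and -0.61. Less bright COL8A1 probe sets above background were at -0.06 and -0.09. COL3A1, a major fibrillar collagen, went the other way at 0.83 ± 0.38 (limma adjusted p = 0.632), on a probe set with a mean of 5.79 in untreated animals. The collagen call was lost without untreated replicate 2 (adjusted p = 0.119) and without high-dose replicate 1 (adjusted p = 0.0649), with the covariate for the neighbouring tag numbers of untreated replicate 2 and low-dose replicate 1 (0.135) and without these 2 animals (0.143).

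Of the 17 macrophage markers, 14 were lower, 0 passed over all probe sets and 2 passed when adjusted over the list alone. These were LAPTM5, a lysosomal protein of blood cells, at -0.80 ± 0.16, and the mannose receptor MRC1 at -1.17 ± 0.28. The scavenger receptor CD163 was at -0.93, with -0.45 on a less bright probe set, and the complement chain C1QC at -0.96. No list of markers of another cell type passed. Endothelial genes had a median of -0.17 over 20 genes (camera adjusted p = 0.131), smooth muscle and pericyte markers -0.08 over 10 genes (0.785), lymphocyte markers -0.03 over 15 (0.785), adipocyte markers -0.05 over 11 (0.314), Schwann cell and nerve genes 0.00 over 9 (0.785), epicardial and mesothelial markers 0.20 over 5 (0.131) and erythrocyte genes -0.43 over 5 (0.061).

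All 19 measured cell cycle genes were lower at the high dose, and the list fell with a median of -0.29 (camera adjusted p = 1.25e-09; adjusted p = 0.244 with an estimated correlation). None passed over all probe sets and 5 passed when adjusted over the list alone. Topoisomerase II alpha (TOP2A), which untangles DNA in dividing cells, measured 7.39 ± 0.48 in untreated animals (SD, n = 3), 6.32 ± 0.65 at the low dose (n = 3) and 4.80 ± 0.04 at the high dose (n = 2). Its change at the high dose was -2.58 ± 0.37 (limma adjusted p = 0.141). Cyclin B1 (CCNB1) was at -1.85, the ribonucleotide reductase subunit RRM2 at -1.44, cyclin B2 (CCNB2) at -0.88 and the replication clamp PCNA at -0.58. Outside the lists, the naming rule also picked the PCNA-associated factor PCLAF at -3.01 ± 0.38 (limma adjusted p = 0.079), the centromere protein CENPH at -1.52 ± 0.18 (0.0634), securin (PTTG1) at -1.28 ± 0.15 (0.0573) and RACGAP1, needed for cytokinesis, which was lower at 3.80 in the high-dose animals, close to background, against 5.88 in untreated ones (0.19).

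All 16 immediate early genes were higher at the high dose. None passed over all probe sets and 10 passed when adjusted over the list alone. The nuclear receptor NR4A2 was at 3.31 ± 0.67, FOS at 2.34 ± 0.68, the antiproliferative gene BTG2 at 2.04 ± 0.53 and KLF4 at 1.52 ± 0.39. Untreated animals differed among themselves by much of that size: FOS measured 9.81 ± 0.91 in untreated animals (SD, n = 3), 9.06 ± 1.23 at the low dose (n = 3) and 12.15 ± 0.14 at the high dose (n = 2). IER5, a stress-induced gene outside the list, was at 1.97 ± 0.29 (limma adjusted p = 0.141) and at 2.09 on its brightest probe set.

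**Figure D1:**
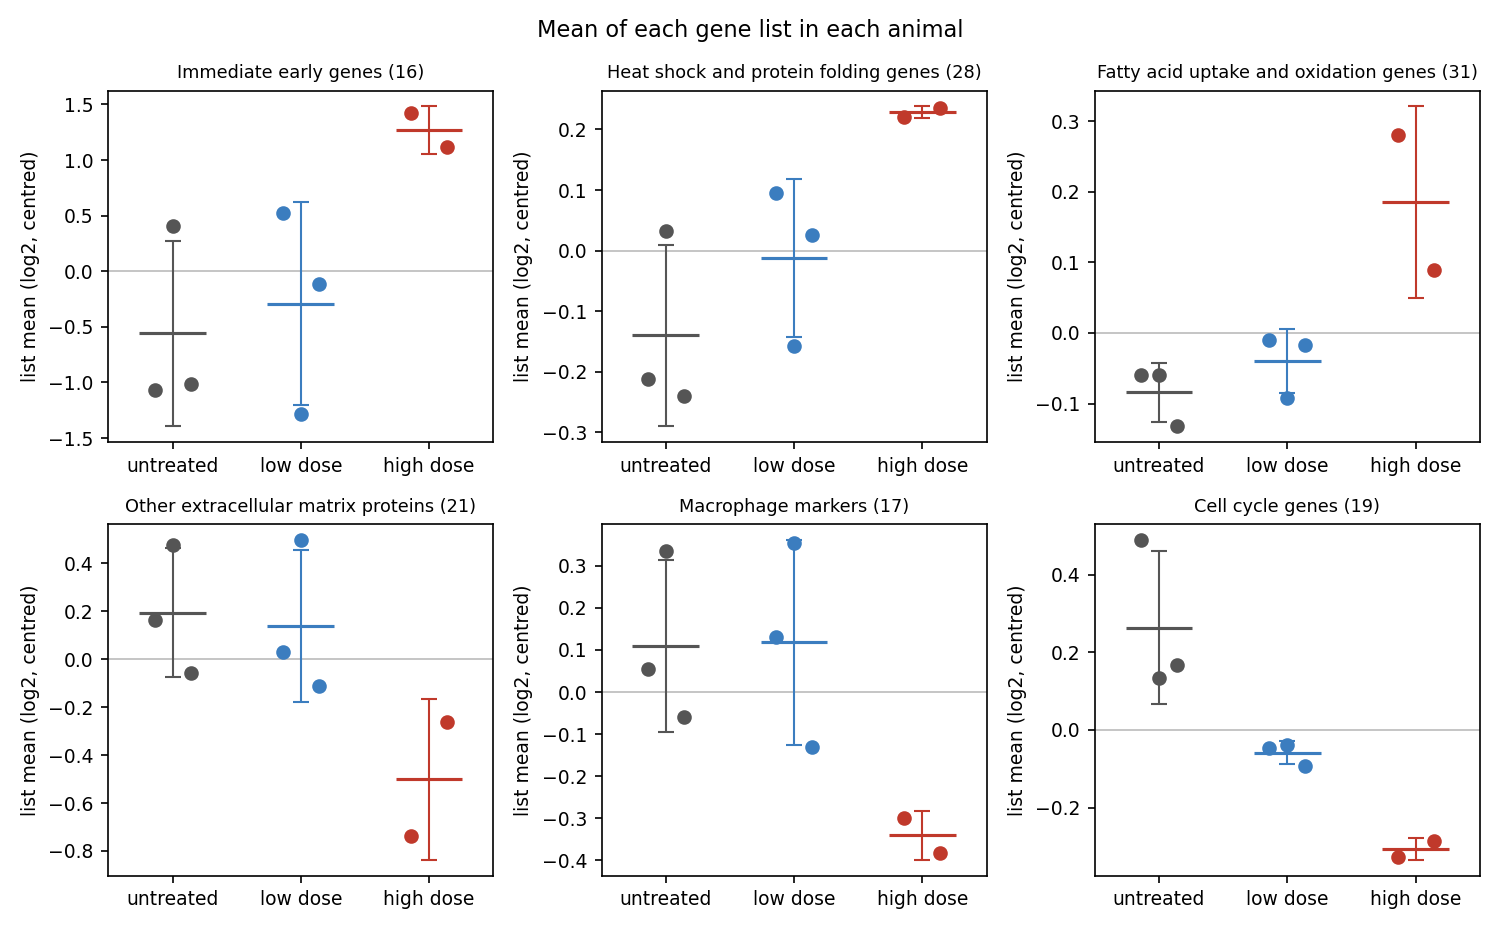
Mean of 6 gene lists in each animal, on the log2 scale after each gene was centred on its mean over the 8 arrays; points are animals, horizontal lines group means and error bars the SD, and the number of genes is in brackets. The 2 high-dose animals lie outside the range of the 3 untreated animals in each of the 6 panels, and for the cell cycle genes the 3 low-dose animals do too. The 6 lists had all passed camera for high dose against untreated. Among all probe sets, 26.6% separated the high-dose from the untreated animals without overlap, and 20% would by chance.

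Heat shock and protein folding genes rose as a list with a median of 0.38, with 22 of 28 higher (camera adjusted p = 9.87e-06; adjusted p = 0.136 with an estimated correlation); 0 passed over all probe sets and 0 when adjusted over the list alone. The chaperones HSPH1, HSPB1 and HSPA8 were at 0.76, 0.71 and 0.61, and HSP70.2, an inducible HSP70, at 1.01 ± 0.17 (limma adjusted p = 0.178) and at 0.54 on its brightest probe set. The dimmer HSPA8 probe sets, with means of 4.91, 4.17 and 3.82 against 13.0, were at -0.15, -0.18 and -0.09. Outside the list HSPA6 was at 1.51 and HSPA13 at 0.85, with 1.20 on its brighter probe set. The small heat shock protein CRYAB was at 1.52 ± 0.27 on a probe set with a mean of 5.74 (limma adjusted p = 0.202), while its brighter probe set, with a mean of 13.1, was at 0.36. Fatty acid uptake and oxidation genes rose with a median of 0.20, with 26 of 31 higher (camera adjusted p = 5.04e-05; adjusted p = 0.244 with an estimated correlation). None passed over all probe sets, and PPARGC1A, a coactivator that drives mitochondrial genes, was the 1 gene to pass over the list alone, at 1.08 ± 0.23. The oxidation enzymes ECI2, ECH1 and ACADVL were at 1.03, 0.72 and 0.49, with 1.02 on a less bright ACADVL probe set, and SIRT3, a mitochondrial deacetylase, at 0.69. Antioxidant and hypoxia genes rose with a median of 0.22, with 19 of 23 higher (camera adjusted p = 0.0255; adjusted p = 0.329 with an estimated correlation); 0 passed over all probe sets and 0 over the list alone. Without high-dose replicate 1 or 2 the list's adjusted p was 0.0649 or 0.0571. Within it the peroxide-reducing GPX3 was at 0.84 and GPX1 at -1.86. With the mean of a gene's probe sets the antioxidant list had 0.0535. With the immediate early gene mean as a covariate, added later, the heat shock and antioxidant calls were lost, with medians of 0.17 (camera adjusted p = 0.324) and 0.11 (0.538).

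Myocardin (MYOCD), a transcription coactivator of cardiac and smooth muscle genes, measured 6.10 ± 0.05 in untreated animals (SD, n = 3), 6.17 ± 0.18 at the low dose (n = 3) and 7.50 ± 0.30 at the high dose (n = 2). Its change at the high dose was 1.40 ± 0.16 (limma adjusted p = 0.0505). The brain natriuretic peptide gene NPPB, a marker of wall stress, was at -2.25 ± 0.59 (limma adjusted p = 0.392) and the atrial peptide gene NPPA at -1.34 ± 0.52 (0.559). The contractile gene MYH7 was at 0.04 ± 0.11 on a probe set close to the top of the scale, the calcium pump ATP2A2 at 0.03 ± 0.12 and smooth muscle actin (ACTA2) at -0.20 ± 0.57. C1QTNF3, a secreted protein, was at -2.98 ± 0.47 (0.141), LAP3 at 1.02 with 0.54 on its brightest probe set, DAP at 0.90, C8G at 0.94 with 0.06 on another probe set, and IREB2, which regulates iron uptake, at -0.83.

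Among the lists that did not pass, the ERBB receptor and ligand list had a median of -0.18 over 5 genes but a mean of 0.80 (camera adjusted p = 0.785). The mean was set by the ERBB ligand amphiregulin (AREG), at 3.63 ± 0.94 (limma adjusted p = 0.384), which passed over the list alone. Fetal and hypertrophy genes had a median of 0.08 (camera adjusted p = 0.477), with NPPB lower and sarcolipin (SLN) higher, at 1.84, when adjusted over the list alone. TGF-beta and myofibroblast genes were at -0.15 (0.061), citric acid cycle genes at 0.09 (0.131), oxidative phosphorylation genes at 0.04 (0.244), glycolysis genes at 0.09 (0.441), sarcomere genes at 0.05 (0.396) and calcium handling genes at 0.07 (0.612). Cytokine genes were at 0.14 (0.251), interferon response genes at 0.01 (0.799), matrix proteases at 0.00 (0.785), apoptosis genes at -0.07 (0.684), PI3K, AKT and MAPK genes at 0.00 (0.684), protein breakdown genes at 0.04 (0.977) and ribosomal protein genes at -0.07 (0.061). Median, mean and test differed in sign for 4 further lists, whose tests all pointed lower: the means were 0.01 for smooth muscle markers, -0.05 for PI3K, AKT and MAPK genes, 0.01 for matrix proteases and -0.01 for protein breakdown genes.

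**Figure D2:**
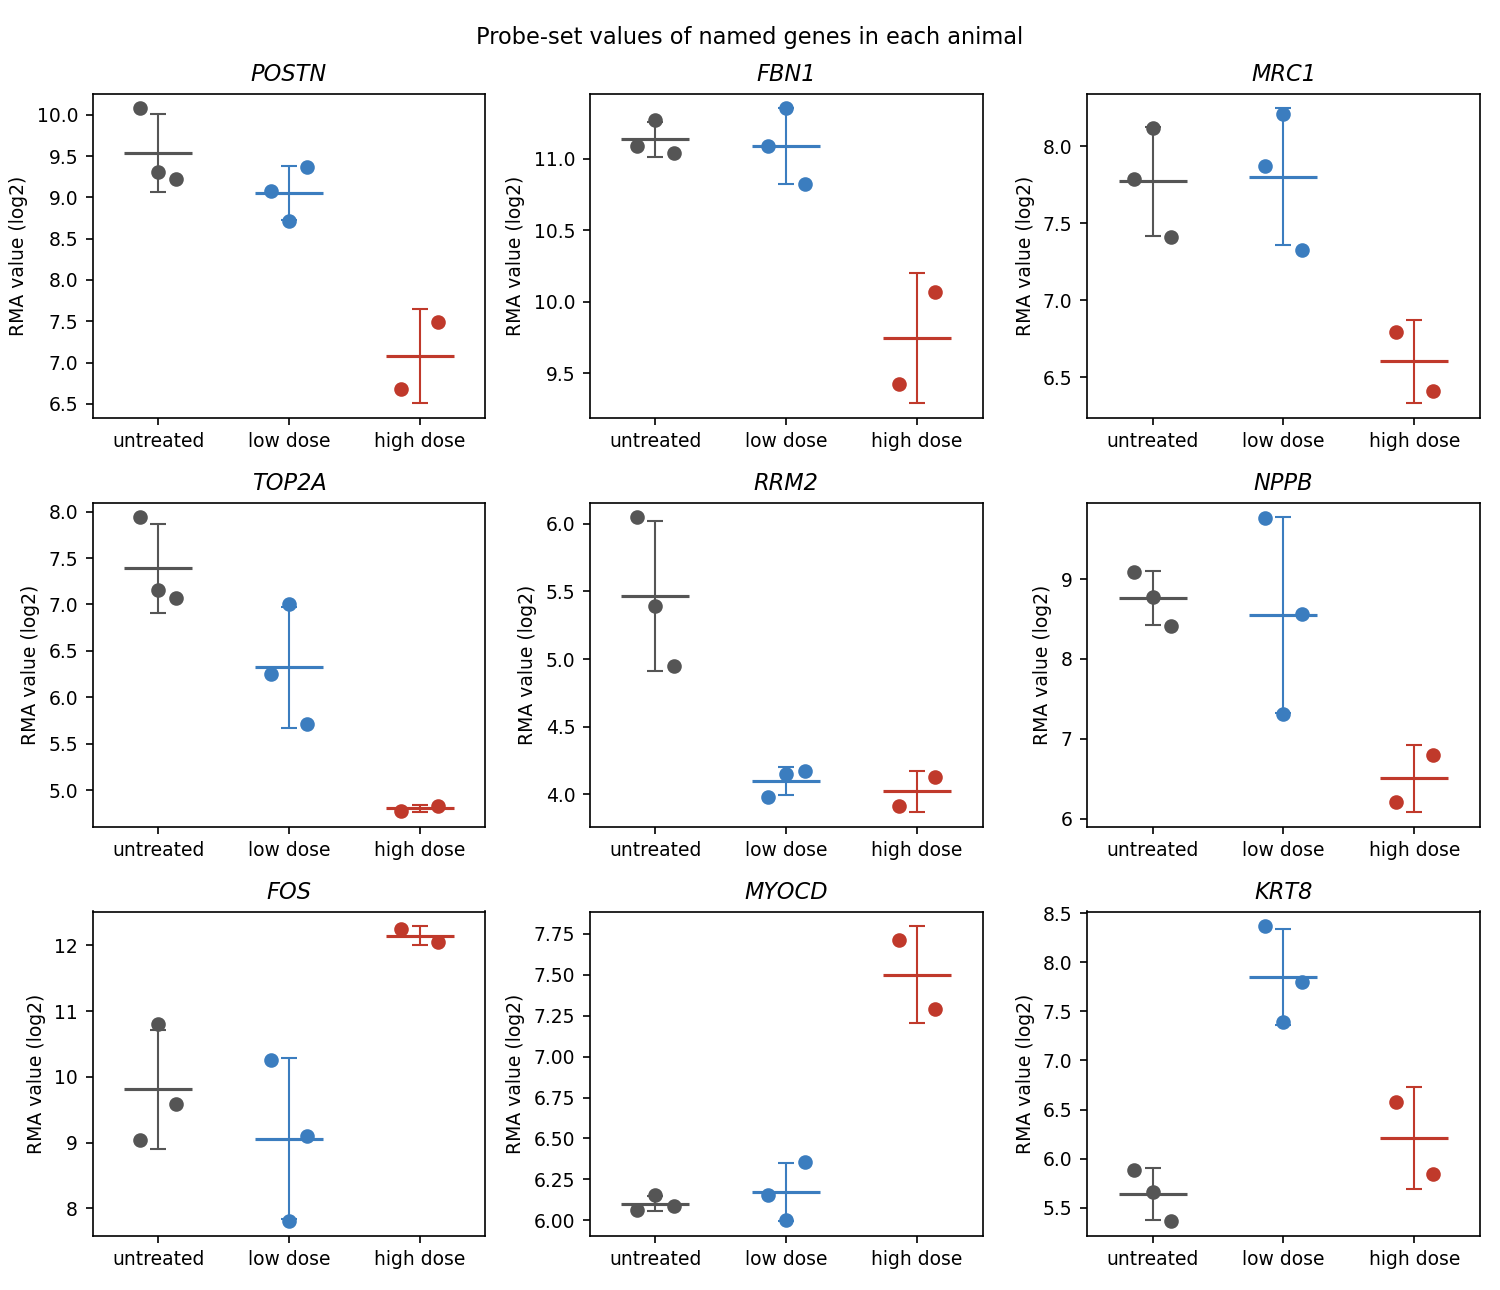
RMA values (log2) of 9 named genes in each animal; points are animals, horizontal lines group means and error bars the SD. POSTN, FBN1, MRC1, TOP2A and NPPB are lowest in the 2 high-dose animals, FOS and MYOCD are highest in them, RRM2 is lower at both doses and KRT8 is highest at the low dose; none of the 9 passed the test over all probe sets.

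The absence of passing probe sets depended on the fit and on single animals. The count was 13 with array weights, 19 without untreated replicate 2, 1 without untreated replicate 1 and 2 without low-dose replicate 1. There were 70 with a covariate, added later, for the neighbouring tag numbers of untreated replicate 2 and low-dose replicate 1, and 55 without these 2 animals. The 2 high-dose animals also carried neighbouring tag numbers, as did untreated replicates 1 and 3, so a feature shared by animals of one tag series could not be separated from the dose.

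The comparison of low dose with untreated asked what the smaller dose changed. Among the lists, the smallest camera p with the preset correlation was that of the cell cycle genes. They fell with a median of -0.27 over 19 genes, 18 of them lower (adjusted p = 7.08e-07; adjusted p = 0.298 with an estimated correlation). None passed over all probe sets and RRM2 passed over the list alone. RRM2 measured 5.46 ± 0.55 in untreated animals (SD, n = 3) and 4.10 ± 0.11 at the low dose (n = 3), a change of -1.36 ± 0.24 (limma adjusted p = 0.998). CCNB1 was at -1.07 and TOP2A at -1.06, and outside the list PCLAF was at -1.35 and PTTG1 at -0.69. With probe sets dimmer than the median left out, the list had an adjusted p = 0.0521.

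Epicardial and mesothelial markers rose with a median of 0.36 over 5 genes, 4 of them higher (camera adjusted p = 0.00393; adjusted p = 0.298 with an estimated correlation). The list was led by keratin 8 (KRT8), a filament protein of epithelia and mesothelium, which measured 5.64 ± 0.26 in untreated animals, 7.85 ± 0.49 at the low dose and 6.21 ± 0.52 at the high dose (SD; n = 3, 3 and 2). Its change of 2.21 ± 0.28 at the low dose did not pass over all probe sets (limma adjusted p = 0.795) and was the 1 member passing over the list alone. KRT19, close to background, was at 0.45, TCF21 at 0.36 and KRT18 at 0.18. Without low-dose replicate 3 the list had an adjusted p = 0.134, and with camera on ranks 0.149.

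Smooth muscle and pericyte markers rose with a median of 0.10, with 9 of 10 higher (camera adjusted p = 0.0475; adjusted p = 0.298 with an estimated correlation). None passed over all probe sets or over the list alone. Calponin (CNN1) was at 1.46, the potassium channel subunit KCNJ8 at 0.50, with 0.19 and -0.10 on less bright probe sets, smoothelin (SMTN) at 0.28 and PDGFRB at 0.09. The call was lost without low-dose replicate 1, 2 or 3, with adjusted p = 0.11, 0.294 and 0.0576, and the median was -0.03 without untreated replicate 3. It was also lost with the mean of a gene's probe sets (0.0646) and with camera on ranks (0.126). Heat shock genes rose with a median of 0.09, with 21 of 28 higher (camera adjusted p = 0.0475; adjusted p = 0.298 with an estimated correlation), and 0 passed over all probe sets or over the list alone. DNAJB1 was at 0.95, HSP70.2 at 0.58 on its brightest probe set, HSPH1 at 0.36 and HSPA5 at 0.31. That call was lost without untreated replicates 1 or 3 (adjusted p = 0.194 and 0.23) and without low-dose replicates 1 or 3 (0.668 and 0.0754), with the mean of a gene's probe sets (0.0738), with the immediate early gene covariate (0.258), with the covariate for the neighbouring tag numbers (0.072) and without those 2 animals (0.259).

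Of the lists that passed at the high dose, 6 did not pass here. Other extracellular matrix proteins had a median of -0.05 (camera adjusted p = 0.508), collagens 0.09 (0.508), macrophage markers 0.01 (0.823), fatty acid genes -0.02 (0.823) and antioxidant genes 0.01 (0.952), while immediate early genes had 0.46 (0.508) with 10 of 16 higher. POSTN was at 9.05 ± 0.33 at the low dose (SD, n = 3). NPPB was at -0.21 ± 0.53, NPPA at -0.57 ± 0.46, COL3A1 at 0.13 ± 0.34, ACTA2 at 0.29 ± 0.51, MYH7 at 0.06 ± 0.10 and ATP2A2 at 0.07 ± 0.10, all with limma adjusted p = 0.998. Other genes picked by the naming rule were ACSS3 (1.13), GMPR2 (0.87), DLG3 (0.74), LOC102157641 (0.72), CREBZF (0.68), ZCCHC8 (0.66), ATP1B4 (0.65, from an untreated level close to background), the discoidin receptor DDR1 (0.63) and DNAJA1 (0.61). On the lower side they were PKIB (-1.17), NREP (-0.82), IREB2 (-0.71), TMEM98 (-0.70), MARCH6 (-0.68), CYB5B (-0.68) and UBXN6 (-0.60). The brighter probe sets of ACSS3 were at 0.27 and 0.16, that of DNAJA1 at 0.25, and the brightest of CREBZF and MARCH6 at 0.36 and 0.15. A less bright one of GMPR2 was at 0.16. The gap between 3' and 5' control probe sets was 3.28 to 3.78 at the low dose and 2.93 to 3.37 in untreated animals. For actin alone it was 5.48 to 6.04 and 4.88 to 5.26, with no overlap, so RNA integrity was not fully matched in this comparison. In all, 0 probe sets passed in limma and 1081 had an unadjusted p under 0.05, against 1200 expected. The other 20 lists had camera adjusted p between 0.318 and 0.954. Median, mean and test differed in sign for the ERBB list (0.15, 0.11 and lower), fatty acid genes (-0.02, 0.04 and lower), citric acid cycle genes (-0.01, -0.01 and higher) and apoptosis genes (0.04, -0.02 and higher).

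**Figure D3:**
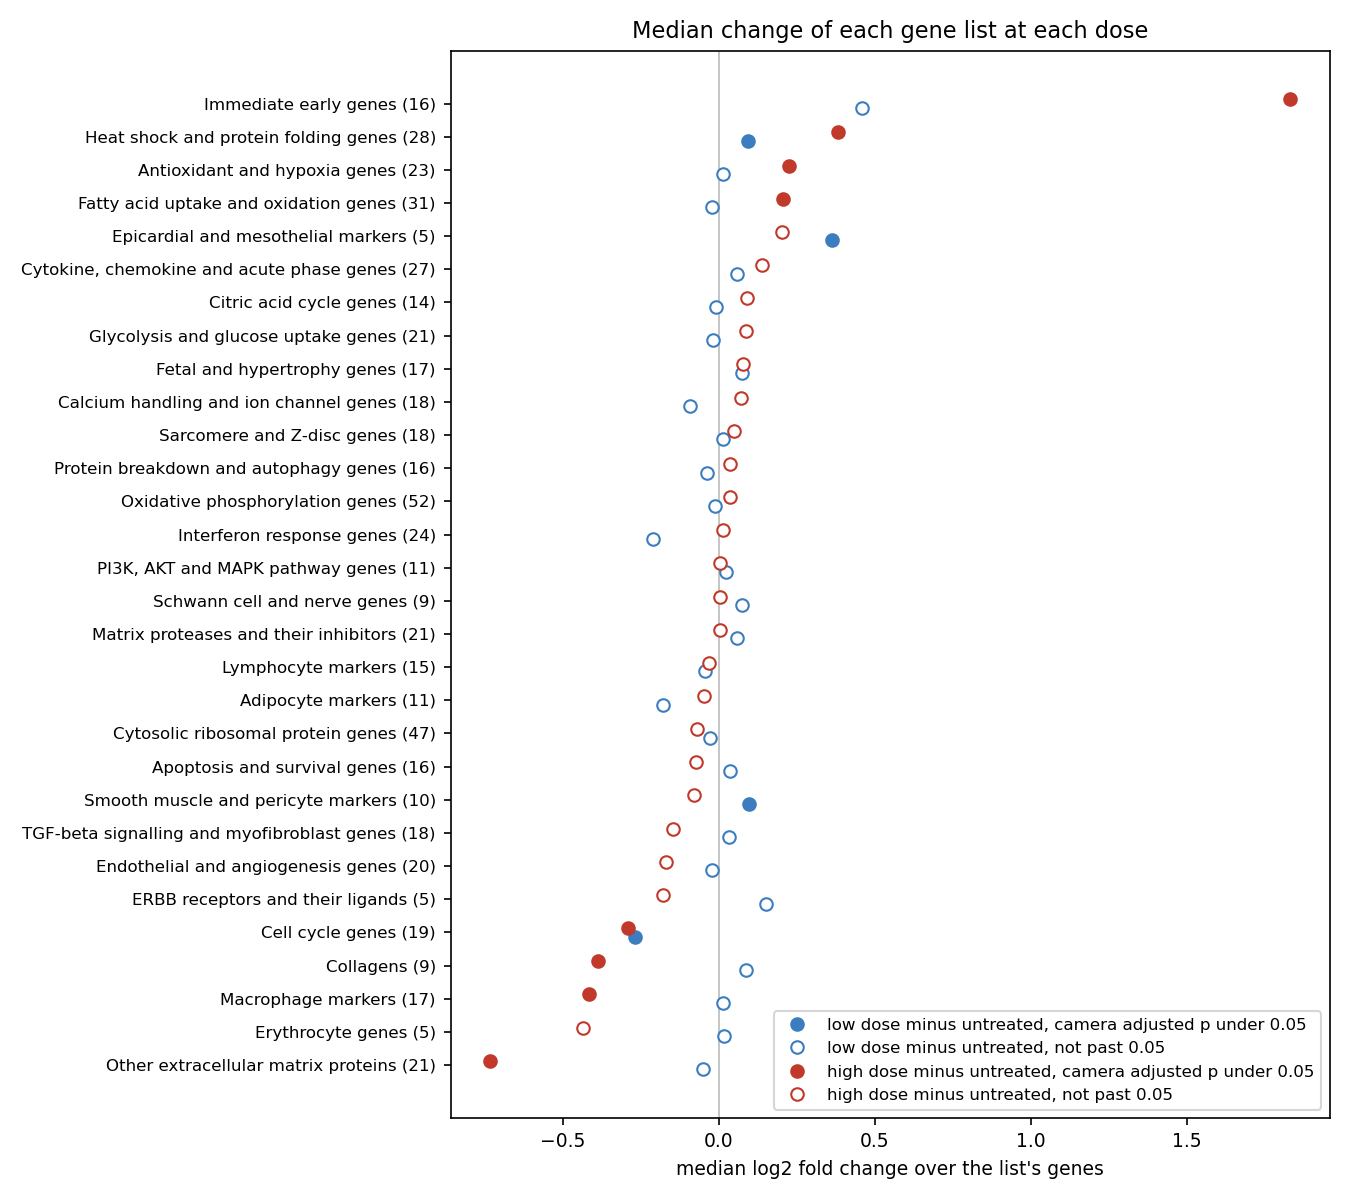
Median log2 fold change of the genes of each of the 30 lists at the low and the high dose, each against untreated; the number of genes is in brackets and filled points have a camera adjusted p under 0.05. Immediate early genes lie farthest right at the high dose (1.83) and other extracellular matrix proteins farthest left (-0.73); cell cycle genes are filled at both doses.

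High dose was compared with low dose to ask whether the doses differed from each other. Matrix, collagen and macrophage genes were lower and immediate early and fatty acid genes higher at the high dose than at the low dose. Other extracellular matrix proteins differed by a median of -0.68, with 19 of 21 lower (camera adjusted p = 9.29e-08), macrophage markers by -0.42, with 15 of 17 lower (3.63e-05), collagens by -0.39, with 7 of 9 lower (0.00177), immediate early genes by 1.43, with 16 of 16 higher (2.86e-07), and fatty acid genes by 0.18, with 26 of 31 higher (5.89e-05). For each of these 5 lists the adjusted p = 0.328 with an estimated correlation. None of their members passed over all probe sets; adjusted over the list alone, 4 matrix, 5 macrophage, 2 collagen, 7 immediate early and 1 fatty acid gene passed.

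FBN1 was at -1.34 ± 0.22 (limma adjusted p = 0.145), POSTN at -1.97 ± 0.33 (0.146), VCAN at -1.70 and LUM at -0.85. COL8A1 was at -1.15, with -0.02 and 0.10 on less bright probe sets. COL15A1 was at -0.70, COL5A1 at -0.83, with -0.48 on a less bright probe set, and COL1A2 at -0.37. LAPTM5 was at -0.89, MRC1 at -1.20, CD163 at -1.03 and the complement chain C1QA at -0.66. FOS was at 3.09, NR4A2 at 2.79, CYR61 at 2.16 and BTG2 at 2.14. PPARGC1A was at 1.24, PPARA, the nuclear receptor for fatty acids, close to background, at 0.64, and ACSL1, which activates fatty acids, at 0.60. The electron carrier ETFDH was at 0.86 on a probe set of intermediate level and at 0.51 on its brightest.

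Heat shock genes differed by 0.20 with 1 member, HSPB3 at 0.70, passing over the list alone (camera adjusted p = 0.0157; adjusted p = 0.328 with an estimated correlation). HSPB1 was at 0.59, HSPA8 at 0.44, with -0.05, -0.04 and -0.04 on its dimmer probe sets, and HSP90AB1 at 0.38. The call was lost without low-dose replicate 2 (0.0668) or high-dose replicate 2 (0.0647). TGF-beta and myofibroblast genes differed by -0.18, with 2 of 18, the protease FAP (-0.74) and the receptor TGFBR1 (-0.51), passing over the list alone (camera adjusted p = 0.0194; adjusted p = 0.499 with an estimated correlation). VIM was at -0.78 and TGFB1 at -0.34. That call was lost without low-dose replicate 2 (0.133) or high-dose replicate 1 (0.156), with the mean of a gene's probe sets (0.0559) and with the covariate for the neighbouring tag numbers (0.0931). Cell cycle genes differed by -0.11, with 14 of 19 lower and 0 passing over the list alone (camera adjusted p = 0.0206; adjusted p = 0.571 with an estimated correlation). TOP2A was at -1.52, CCNB1 at -0.78, the cell cycle inhibitor CDKN1A at -0.68 and CCNB2 at -0.54. The call was lost without low-dose replicate 1 (0.0831) or high-dose replicate 1 (0.0692), without dim probe sets (0.0863) and without the 2 animals with neighbouring tag numbers (0.126). Erythrocyte genes differed by -0.50, with ALAS2 (-0.54), HBM (-0.57) and AHSP (-0.50) passing over the list alone, while HBB was at 0.22 (camera adjusted p = 0.0271; adjusted p = 0.328 with an estimated correlation). That call was lost without low-dose replicates 2 or 3 (0.0757 and 0.0815) or high-dose replicate 2 (0.0575) and with camera on ranks (0.116), and AHSP lay close to background. Antioxidant genes differed by 0.21, with 0 of 23 passing over the list alone and MT1A at 0.71, CA9 at 0.44, GPX3 at 0.55 and GPX1 at -1.96 (camera adjusted p = 0.0271; adjusted p = 0.328 with an estimated correlation). It was lost without low-dose replicate 2 (0.108) or high-dose replicates 1 or 2 (0.0908 and 0.0644), with the mean of a gene's probe sets (0.0743) and without dim probe sets (0.052). With the immediate early gene covariate these 5 calls were lost, with adjusted p = 0.917 for heat shock, 0.139 for TGF-beta, 0.471 for cell cycle, 0.5 for erythrocyte and 0.471 for antioxidant genes. In none of these 5 lists did a member pass over all probe sets.

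In limma 6 probe sets passed, 1 higher and 5 lower at the high dose, and none of the 6 carried a gene symbol. The largest decrease was from 9.12 ± 0.19 at the low dose (SD, n = 3) to 6.84 ± 0.46 at the high dose (n = 2), and the 1 increase was to 4.81 ± 0.08 from a low-dose level of 3.29, which is close to background and gives no exact size of change. Among named genes the smallest p belonged to MYOCD, at 1.33 ± 0.16 (limma adjusted p = 0.0591), and CREBZF, at -1.22 ± 0.16 (0.0832) with -0.57 on its brightest probe set. CENPH was at -1.17, the kinase PLK2 at 2.38, IER5 at 1.67 and PTGES3 at 0.72, with 0.37 on the brighter probe set of PTGES3. OAZ1 was at -2.78 on 1 probe set, whereas its other probe set was at 0.02 at each dose against untreated. NPPB was at -2.04 ± 0.59 (0.305), NPPA at -0.77 ± 0.52 (0.667), COL3A1 at 0.70 ± 0.38 (0.586), ACTA2 at -0.49 ± 0.57 (0.825), MYH7 at -0.02 ± 0.11 (0.975) and ATP2A2 at -0.04 ± 0.12 (0.936). The count of 6 fell to 0 without untreated replicates 1 or 3, low-dose replicates 2 or 3 or high-dose replicate 1, and to 1 without high-dose replicate 2. A fit of only these 2 groups gave 0, and 1 passed without dim probe sets; with the covariate for the neighbouring tag numbers 25 passed. The gap between 3' and 5' control probe sets did not overlap between the low dose (3.28 to 3.78) and the high dose (3.00 to 3.04), so RNA integrity differed along with dose in every gene and list of this comparison. The other 20 lists had camera adjusted p between 0.0736 and 0.895, and median and mean differed in sign for sarcomere genes (0.00 and 0.06) and fetal genes (-0.01 and 0.08).

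The mean of both doses was compared with untreated to ask what GGF2 treatment changed on average over the doses. A call here can come from 1 dose alone. Cell cycle genes had the smallest camera p with the preset correlation, and their mean was lower in all 5 treated animals than in the 3 untreated ones. With the correlation estimated, heat shock genes ranked before them. The cell cycle list fell with a median of -0.26, with 18 of 19 lower (camera adjusted p = 2.13e-11; adjusted p = 0.245 with an estimated correlation). The list mean was 0.26 ± 0.20 in untreated animals (SD, n = 3), -0.06 ± 0.03 at the low dose (n = 3) and -0.31 ± 0.03 at the high dose (n = 2), and the exact permutation test of treated against untreated gave p = 0.0357, the smallest it can give, and 0.804 after Benjamini-Hochberg adjustment over the 30 lists. None of the genes passed over all probe sets; TOP2A (-1.82), CCNB1 (-1.46), RRM2 (-1.40), CCNB2 (-0.61) and PCNA (-0.44) passed when adjusted over the list alone.

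Outside the lists the naming rule picked PCLAF at -2.18 ± 0.31 (limma adjusted p = 0.463), PTTG1 at -0.98 ± 0.12 (0.331), the mitotic kinase MELK at -1.27, down to a level close to background, and stathmin (STMN1), which regulates microtubules, at -0.76. IREB2 was at -0.77, NREP at -0.93 and PKIB at -1.24. On the higher side were CRYAB at 1.15 ± 0.22 (0.542) on the less bright of its probe sets, HSP70.2 at 0.75 ± 0.14 (0.514) and at 0.56 on its brightest probe set, DAP at 0.69, ATP1B4, close to background, at 0.61, PAAF1 at 0.64, with 0.11 and 0.55 on others, and LOC102157641 at 0.60. Probe sets disagreed for ACSS3, at 0.82 on its dimmest and at -0.01 and -0.14 on the brighter ones, and for EIF4H, at 0.87 on the dimmer and -0.15 on the brighter. NPPB was at -1.23 ± 0.47, NPPA at -0.96 ± 0.42 and COL3A1 at 0.48 ± 0.30 (each 0.956), ACTA2 at 0.04 ± 0.46, MYH7 at 0.05 ± 0.09 and ATP2A2 at 0.05 ± 0.09. In all, 0 probe sets passed in limma and 1160 had an unadjusted p under 0.05, against 1200 expected.

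Immediate early genes rose with a median of 0.96, with 16 of 16 higher (camera adjusted p = 2.54e-07; adjusted p = 0.497 with an estimated correlation), and other extracellular matrix proteins fell with a median of -0.35, with 20 of 21 lower (2.54e-07; adjusted p = 0.497 with an estimated correlation). NR4A2 was at 1.92, NR4A3 at 1.88 and KLF4 at 0.96; POSTN was at -1.47, FBN1 at -0.72, LUM at -0.47 and LAMB1 at -0.41. Heat shock genes rose with a median of 0.20, with 24 of 28 higher (camera adjusted p = 6.83e-06, and 0.128 with an estimated correlation), among them DNAJB1 (1.11), HSPH1 (0.56), HSPA8 (0.39) and HSPA5 (0.37). The dimmer HSPA8 probe sets were at -0.13, -0.16 and -0.07. Macrophage markers fell with a median of -0.18, with 14 of 17 lower (0.00326; adjusted p = 0.683 with an estimated correlation). VSIG4 was at -0.62, MRC1 at -0.57, CTSS at -0.38 and LAPTM5 at -0.36. The macrophage list had a median of -0.04 and an adjusted p = 0.309 without untreated replicate 2, and an adjusted p = 0.252 without the 2 animals with neighbouring tag numbers. Epicardial markers rose with a median of 0.25, with 5 of 5 higher (0.00475; adjusted p = 0.497 with an estimated correlation), led by KRT8 at 1.39, with KRT19, close to background, at 0.34, TCF21 at 0.25 and KRT18 at 0.19. Without untreated replicate 3 the adjusted p was 0.0587. Fatty acid genes rose with a median of 0.09, with 22 of 31 higher (0.0109; adjusted p = 0.497 with an estimated correlation), among them ECI2 (0.82), PPARGC1A (0.46), ACADVL (0.32) and ETFB (0.27). Without untreated replicate 2 or high-dose replicate 1 the adjusted p of that list was 0.0668 or 0.124, and without the 2 animals with neighbouring tag numbers 0.0691. With the immediate early gene covariate the heat shock, epicardial and fatty acid calls were lost, with medians of 0.09, 0.24 and 0.07 (camera adjusted p = 0.0836, 0.0789 and 0.0791). No member of these 6 lists passed over all probe sets, while 2 matrix genes and 1 epicardial gene passed when adjusted over the list alone. Of these lists, only heat shock genes passed at each single dose against untreated with the preset correlation. Immediate early, matrix, macrophage and fatty acid genes passed only at the high dose, and epicardial markers only at the low dose. KRT8 was at 2.21 at the low dose and at 0.57 at the high dose. The other 23 lists had camera adjusted p between 0.171 and 0.999. Median and mean differed in sign for TGF-beta genes (-0.07 and 0.01), protein breakdown genes (0.03 and -0.05) and the ERBB list (-0.09 and 0.46), and the test for calcium handling genes pointed higher with both below 0 (-0.01 and -0.02).

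The fold changes of the low and the high dose correlated at 0.320 across probe sets, which are not independent replicates. Both were taken against the same 3 untreated arrays. Simulated arrays of unchanged groups, with genes varying independently, gave a correlation of 0.447 ± 0.011 from the shared untreated arrays alone. The observed one lay below that mean. Leaving out 1 array moved it to 0.150 without low-dose replicate 1 and to 0.551 without untreated replicate 2. The covariance was 0.01995 against 0.01708 ± 0.00059 simulated (SD, 100 simulations). At an unadjusted p under 0.05 with at least 1.5-fold change, 17 probe sets were higher at both doses, against 20.9 simulated and 1.75 for independent lists, and 42 were lower at both, against 20.6 simulated and 1.62 for independent lists. The SD over the simulations was 4.11 for the higher and 4.29 for the lower calls. The simulated genes were independent, and no likeness between single animals of different groups was simulated. The simulated SDs are therefore too narrow a measure to decide whether the 2 doses share an effect. Probe sets called in opposite directions numbered 4, against 4.09 for independent lists. The 3 untreated arrays could not be divided into 2 sets of 2 to test this with separate controls.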

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

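The tests of explanations in this part were chosen after the results had been seen, except the counts over other groupings of the arrays, whose predictions were written before those counts were made. The results listed here stand apart because the effect of the high dose differed from that of the low dose, each against the same untreated animals, by a direct test of the difference. Camera gave an adjusted p under 0.05 for the lists that follow, each with the median over its genes of the high-minus-low change. These medians were -0.68 in other extracellular matrix proteins, 1.43 in immediate early genes, -0.42 in macrophage markers, 0.18 in fatty acid genes, -0.39 in collagens, 0.20 in heat shock genes, -0.18 in TGF-beta and myofibroblast genes, -0.11 in cell cycle genes, 0.21 in antioxidant genes and -0.50 in erythrocyte genes. None of these 10 passed with an estimated correlation. With the immediate early gene mean as a covariate 5 of them, besides the immediate early genes, also ended: heat shock genes at 0.01 (camera adjusted p = 0.917), antioxidant genes at 0.13 (0.471), cell cycle genes at -0.09 (0.471), erythrocyte genes at -0.11 (0.5) and TGF-beta genes at -0.09 (0.139). The gap between 3' and 5' control probe sets was 3.28 to 3.78 at the low dose and 3.00 to 3.04 at the high dose, so RNA quality was not excluded for these differences. In limma, 6 probe sets without a gene symbol passed, with differences of -2.27, -1.99, -1.62, 1.52, -1.85 and -1.38; the 1.52 was measured from a level close to background and the -1.99 down to one, so neither is an exact size.

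Immediate early genes were higher in the high-dose animals. The mean of the list differed among the 3 untreated animals over a range of 1.47, which is 0.806 of the difference of 1.83 between high dose and untreated, so differences between animals that do not follow the dose could account for much of it. These genes respond within minutes to stress and to tissue handling, for which the labels give no record. For high dose against untreated, the gap between 3' and 5' control probe sets differed by only -0.092. It lay between 3.00 and 3.04 in the high-dose animals, within the untreated range of 2.93 to 3.37. This measure gave no sign of more RNA degradation at the high dose. It rests on control transcripts and on 2 high-dose arrays, so smaller differences in RNA quality are not excluded. An effect of the dose also remains open, with all 16 genes higher.

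Matrix and macrophage genes were lower in the high-dose animals. A larger share of cardiomyocytes in the tissue pieces would lower the markers of all other cell types alike. Bright matrix genes fell farther than bright endothelial genes, with a difference of -0.59 (95% interval -1.07 to -0.10). The endothelial list also holds angiogenesis genes, and its members ran from -0.57 to 0.94 at the high dose. It is thus a mixed measure of other cell types, and the gap does not settle whether the cardiomyocyte share differed. For macrophage markers the difference from endothelial genes was -0.49 (-0.98 to 0.00), and since the interval reaches 0 a larger cardiomyocyte share cannot be told apart from fewer macrophages there. With the immediate early gene mean as a covariate the matrix median was -0.41 (camera adjusted p = 1.04e-05; -0.73 without it) and the macrophage median -0.46 (0.000273; -0.42 without it), both lost with an adjusted p = 0.53 with an estimated correlation, and between animals the list means then differed by -0.60 (95% interval -1.89 to 0.69) and -0.49 (-1.36 to 0.38), so the state that the immediate early genes follow remains open for both. Less matrix production by fibroblasts at the high dose remains open and might be tested in tissue sections.

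Cell cycle genes were lower at both doses. The fall did not rest on untreated replicate 1, the highest, alone. Without it the median was -0.21, against -0.26 with all animals (camera adjusted p = 8.31e-09, and 0.0708 with an estimated correlation). The list mean still differed by -0.31 between treated and untreated animals (95% interval -0.57 to -0.04). The list was picked for its small camera p and few untreated animals remained, so other differences between animals were not excluded. Fewer dividing macrophages could lower the same genes, but the macrophage mean differed by 0.00797 at the low dose (95% interval -0.42 to 0.43), an interval too wide to settle it. Less division of cells in the treated tissue remains open, and the arrays do not say in which cells.

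Other groupings of the same arrays were run through the same steps; the shares below count the real grouping too, and the highest counts are those of the others. Where the real grouping has 0 probe sets, every grouping has at least as many by construction and nothing is tested: 10 of 10 for low dose against untreated (highest 150), 100 of 100 for high dose against untreated (highest 107) and 100 of 100 for both doses (highest 208). For low dose against untreated 6 of 10 groupings gave at least the 4 lists of the real one (highest 10); 10 groupings are too few to exclude chance. For high dose against untreated, 20 of 100 gave at least 8 lists (highest 12). For high dose against low dose, 4 of 100 gave at least 6 probe sets (highest 107), a share under 0.05, and 14 of 100 at least 10 lists (highest 12). The count of 6 was itself unstable. It was 0 in a fit of only these 2 groups and without some single untreated or low-dose arrays, so that share does not exclude chance. For both doses, 36 of 100 gave at least 7 lists (highest 12). For each of the list counts out of 100, the other groupings had a median of 5 lists. None of those shares was under 0.05, so these list counts do not set the real grouping apart from other groupings of the animals. The groupings with the most probe sets kept untreated replicates 1 and 3 with low-dose replicate 2, apart from untreated replicate 2 and low-dose replicate 1, which points to a structure among the animals that does not follow the dose.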

How the results depend on the processing

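The alternatives with the immediate early gene mean, with neighbouring tag numbers and with permuted list means were chosen after the results had been seen. No paired analysis was possible because the labels hold no replicate numbers, each pig is in 1 group, and neighbouring tag numbers link only 1 pair of animals across groups; the fits that set this pair apart are given below. For high dose against untreated, the immediate early, matrix, cell cycle, heat shock, macrophage and fatty acid lists kept their call in 11 of 11 planned settings besides the estimated correlation. All of these settings kept the preset correlation, so their p-values also leave out most of the variation between animals that the genes of a list share. Where an array was left out and a group had 1 left, that animal was taken to vary like the others. Except where fewer animals were fitted or another threshold was used, the cause was not tested.

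Probe sets passing for high dose against untreated, 0 in the reported fit, were 4 with an intensity trend, 7 with a robust prior, 3 after median centring, 9 after renewed quantile normalization, 2 with only the 2 groups, 13 with array weights, 10 at adjusted p under 0.10, 0 to 19 with arrays left out in turn, 70 with a covariate for the 2 animals with neighbouring tags and 55 without them. For high dose against low dose, 6 in the reported fit, they were 1 without dim probe sets, 0 with only the 2 groups, 10 with array weights, 14 at adjusted p under 0.10, 0 to 7 with arrays left out, 25 with the tag covariate and 12 without the 2 animals. Without the 2 animals, 1 passed for low dose and 1 for both doses against untreated. At an unadjusted p under 0.05 with 1.5-fold change there were 229 for low dose, 782 for high dose, 940 for high against low dose and 295 for both doses.

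Lists passing were 0 in all 4 comparisons with an estimated correlation, and 0 for both doses with exact permutation of list means. For low dose, 4 in the reported fit, they were 2 with the mean of a gene's probe sets, 2 without dim probe sets, 2 with camera on ranks and 2 to 7 with arrays left out. They ran from 7 to 10 for high dose, from 7 to 10 for high against low dose and from 5 to 9 for both doses with arrays left out.

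Some values turned in sign. MYH7, high against low dose, was 0.0236 after median centring and -0.0549 to 0.0031 with arrays left out. With arrays left out, ACTA2 ran from -0.31 to 0.69 at the low dose, -0.60 to 0.0566 at the high dose, -0.89 to 0.10 for high against low dose and -0.36 to 0.30 for both doses. At the low dose COL3A1 ran from -0.19 to 0.44, NPPB from -0.82 to 0.41, PDGFRB from -0.0577 to 0.21, ATP2A2 from -0.00187 to 0.12 and the smooth muscle median from -0.0269 to 0.22. For high against low dose NPPA ran from -1.83 to 0.29 and ATP2A2 from -0.098 to 0.0284, and TCF21 for both doses from -0.092 to 0.63. The correlation of the 2 doses' fold changes ran from 0.150 without low-dose replicate 1 to 0.551 without untreated replicate 2.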

Other observations

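The fits in this part were chosen after the results had been seen. An untreated and a low-dose animal carried neighbouring tag numbers, and a covariate that set these 2 apart left 70 probe sets passing for high dose against untreated in limma, 47 higher and 23 lower, of which 38 carried a gene symbol. This untreated animal, replicate 2, had an immediate early gene mean of 0.41, against -1.07 and -1.01 in the other untreated animals. It thus lay nearest the high-dose animals, and setting it apart can widen the contrast. The other untreated animals and the high-dose animals were each a pair with neighbouring tag numbers. A feature of a tag series therefore cannot be told apart from the dose in these calls. The genes named here are a selection of those passing. Among those higher at the high dose were the ERBB ligand amphiregulin (AREG) at 4.45 (limma adjusted p = 0.0135), the cochaperone BAG3 at 1.46 (0.016), the actin-binding XIRP1 of intercalated discs at 2.16 (0.016), IFRD1 at 3.81 (0.017), the immediate early genes FOSL1 at 1.93 (0.0273) and NR4A3 at 4.35 (0.0274), the amino acid transporter SLC38A1 at 1.36 (0.0274), MYOCD at 1.41 (0.0345), the chemokine CCL2 at 1.80 (0.0345), ABRA, which promotes serum response factor signalling in striated muscle, at 2.15 (0.0362) and the lamin LMNA at 1.51 (0.0434). Among those lower were CENPH at -1.63 (0.016), PTTG1 at -1.29 (0.0345), PCLAF at -3.10 (0.0345), POSTN at -2.51 (0.0403) and KLF15, a repressor of cardiac hypertrophy, at -1.42 (0.0371). For B2M and OAZ1, 1 probe set each was lower too, at -2.87 (0.0345) and -2.86 (0.0345). In the reported fit that B2M probe set was at -2.56. It was not the brightest of B2M, which was in the interferon list, where no member lay below -1.1 at the high dose. When the 2 animals were left out instead, 55 passed and 33 were shared, among them AREG, BAG3, XIRP1 and CENPH but not POSTN (0.0685) or MYOCD (0.0581).

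With the immediate early gene mean as a covariate, 3 mitochondrial lists passed at the high dose with the preset correlation: oxidative phosphorylation genes with a median of 0.19 (camera adjusted p = 3.15e-05), citric acid cycle genes with 0.26 (0.00346) and fatty acid genes with 0.17 (0.0129), as did calcium handling genes with 0.22 (0.0211) and adipocyte markers with -0.36 (0.0262). All 5 calls were lost with the correlation estimated, each with an adjusted p = 0.53 with an estimated correlation. Of these lists, only the fatty acid genes passed without the covariate. Both high-dose animals had a higher immediate early gene mean than any other animal, so these medians rest on extrapolation. In that fit heat shock genes had a median of 0.17 (0.324) and antioxidant genes 0.11 (0.538).

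The deviations from the group means correlated at 0.352 between untreated replicate 2 and low-dose replicate 1, at 0.276 between untreated replicate 1 and low-dose replicate 2 and at -0.376 between untreated replicate 1 and low-dose replicate 1. On the leading principal component, with 32.0% of the variance, untreated replicate 2 and low-dose replicate 1 lay at 10.2 and 17.6, on the side of the high-dose animals at 33.2 and 21.3, and the other untreated animals at -28.1 and -23.4.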
